A study of Mus musculus with 19 samples.

How the data were processed

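Transcript levels were measured in 19 mouse hearts on Affymetrix whole-transcript arrays with 41345 probe sets. The hearts were perfused by the Langendorff method and frozen after 20 min of reperfusion that followed 20 min without flow. Biotinylated DNA for the arrays was made from 300 ng of total RNA. There were 7 hearts of wild-type mice at ZT0, 7 of wild-type mice at ZT12 and 5 of Rev-erb alpha knockout mice at ZT12. Replicates are called biological in the labels, so each array was taken as a separate heart. The labels give the strain C57Bl6J for the wild-type mice and none for the knockout mice, and they name no batch or date.

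The deposited values were probe set summaries that the authors made with RMA, which corrects background, normalizes quantiles across arrays and summarises probes. The deposited scale was taken as log2, since values ran from 0.21 to 12.88 with array medians of 3.25 to 3.32. The software version of RMA and the annotation behind it are not given in the sources used here. All 19 columns of values were used.

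Probe sets were named from the GEO platform annotation, which can be older than current gene models. Its Entrez identifiers were looked up in a reference gene table of GRCm38.p6, which changed 0 symbols and held 23328 of the 23521 probe sets that list 1 gene. Of all probe sets, 1814 listed several genes and 16010 listed none, and these were left out of the gene tests. Of the 22180 genes tested, 1082 had more than 1 probe set and were represented by the probe set with the highest mean over all arrays. The lowest correlation between arrays was 0.972, the highest 0.985. Differences between arrays of the same group had an SD of 0.367 to 0.471, so no array was a copy of another.

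Groups were compared with limma 3.58.1 in R 4.3.3, in a single linear model with 1 mean per group over all 19 arrays, followed by eBayes without trend. The contrasts were wild type at ZT12 minus ZT0, knockout minus wild type at ZT12, and knockout at ZT12 minus wild type at ZT0. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 22180 genes, and a gene was called changed at an adjusted p under 0.05. Log2 values in the text are differences of group means, with the SE of limma. Genes that changed in the same direction from wild type at ZT12 in the knockout and at ZT0 were counted. The count was set beside 100 simulated sets of unchanged groups with shared controls, and beside the 70 ways of dividing the wild-type ZT12 arrays between the comparisons.

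Gene lists were written from general knowledge. They covered clock and other genes repressed by REV-ERB proteins, clock genes with E-box or D-box control, immediate early genes, heat shock, fatty acid uptake and oxidation, glycolysis, oxidative phosphorylation, p53 targets, hypoxia targets, cytokines, antioxidant genes, autophagy, the unfolded protein response, ion channels and calcium handling, fetal and stress genes, extracellular matrix, glucocorticoid-responsive genes, lipid synthesis and cell division. A further 14 lists held markers of cell types and tissues, from cardiomyocyte and atrial muscle to lung and thymus. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists within a comparison, and again with an estimated correlation and with fry. The counts of called genes were also made with p-values adjusted over the list alone. Sex-linked genes were reported as values.

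Genes named in the text were chosen by a rule: the 8 largest rises and 8 largest falls among called genes in each of the comparisons between times and between genotypes, and the 4 of each in the other comparison, leaving out clone names, predicted genes and small RNAs. To these were added all clock list genes, up to 3 called genes per list, or 2 genes with the smallest p where none was called, the 5 shared genes with the largest changes in each direction, and the sex-linked genes. Of the largest rises between the times of day, 1 is not reported. Genes outside the rule that are named below, such as those of the atrial arrays, the neighbours of Nr1d1 and the 4 genes with opposite shared changes, were chosen after their values were seen.

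The analysis was tested on simulated data in which 50 genes each were shifted by 0.25, 0.5, 1 or 2 log2 units among 22180 genes with the spread of the real arrays. Between the wild-type groups 4%, 72%, 98% and 98% of these genes were recovered with the right sign, and 4.90% of calls were false. For knockout against wild type at ZT12 the shares were 6%, 52%, 96% and 100%, with 2.31% false. For knockout against wild type at ZT0 they were 6%, 66%, 96% and 100%, with 3.60% false. Changes of 0.25 were thus mostly missed. A list shifted by 0.2 was found, and 0 of the 32 other lists were called. The genes were simulated independently, so lists whose genes vary together were not put to this test. Random splits of the real arrays called up to 11 lists between the times of day and up to 16 between the genotypes.

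Alternatives were quantile normalization of the deposited values again, centring each array on its median, leaving out dim probe sets (a mean below 3.25), averaging the probe sets of a gene, testing every probe set unmerged, fitting only the arrays compared, array weights, eBayes with trend and robust, a replicate block, and leaving out each array in turn. Stricter thresholds were an adjusted p under 0.01 and at least 1.5-fold. Splits of the samples at random (100 per comparison, fixed seed) gave counts for mixed groups to set beside the real ones. The mean of the atrial list or the value of Bmp10 as a covariate, and leaving out the 4 arrays with low atrial markers, were added after these markers were seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.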

Results

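Transcript levels were measured on Affymetrix arrays in 19 isolated mouse hearts, 1 array per heart. Each heart was perfused by the Langendorff method, in which buffer is pumped backwards through the aorta, and went through 20 min of stabilisation, 20 min without flow and 20 min of reperfusion. The hearts came from wild-type mice at ZT0, the time of lights on (n = 7), from wild-type mice at ZT12, the time of lights off (n = 7), and from Rev-erb alpha knockout mice at ZT12 (n = 5). The labels list no heart without ischemia and no knockout at ZT0, so the values describe reperfused hearts. The array values were log2 intensities with medians between 3.25 and 3.32, and 22180 genes were tested. Correlations between arrays over all probe sets lay between 0.972 and 0.985. The number of arrays per group limits the precision, and the median SE of a log2 difference was 0.096 between the wild-type groups and 0.11 in the comparisons with the knockout. Transcripts of the Y chromosome were present and Xist was at 2.20, 2.18 and 1.97 in the ZT0, ZT12 and knockout hearts, below the array medians. Uty was at 6.51, 6.65 and 6.70, Eif2s3y at 7.05, 7.34 and 7.18, and Kdm5d at 4.87, 4.99 and 5.02 in the same order.

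The comparison of wild-type hearts at ZT12 with those at ZT0 asked how time of day sets the transcripts of the reperfused heart. Arntl, which encodes the clock activator BMAL1, fell 9.08-fold, from 7.27 ± 0.060 at ZT0 to 4.08 ± 0.21 at ZT12 (SD, n = 7 each). Its relative Npas2 was 2.73-fold lower (log2 difference -1.45, SE 0.13; adjusted p = 8.23e-07). Dbp, a transcription factor gene driven by the clock, rose 5.75-fold, from 5.56 ± 0.29 to 8.09 ± 0.10 (SD, n = 7 each). The period gene Per3 rose 3.09-fold (log2 difference 1.63, SE 0.098; adjusted p = 1.16e-09), and Ciart, which encodes a clock repressor, rose 2.77-fold (log2 difference 1.47, SE 0.15; adjusted p = 5.15e-06). Nr1d2, the gene of Rev-erb beta, was 2.495-fold higher at ZT12 (log2 difference 1.32, SE 0.087; adjusted p = 3.74e-09).

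Genes outside the clock were also among the largest changes between the times of day. Tcap, which encodes the titin cap protein of the sarcomere, rose 2.27-fold, from 8.81 ± 0.22 to 9.99 ± 0.069 (SD, n = 7 each). Zbtb16, the gene of a zinc-finger repressor, rose 2.79-fold (log2 difference 1.48, SE 0.093; adjusted p = 1.78e-09). A rise was also found for Gstt2, a glutathione transferase gene (2.05-fold; adjusted p = 4.27e-05). Slc41a3, which encodes a magnesium transporter, fell 2.56-fold (log2 difference -1.36, SE 0.094; adjusted p = 7.40e-09), and the matrix protein gene Spon2 fell 2.56-fold (log2 difference -1.36, SE 0.17; adjusted p = 5.80e-05). The metalloprotease gene Adam19 was 1.95-fold lower (adjusted p = 3.80e-05), with another, dim probe set of the gene at a log2 difference of -0.24. Cdkn1a, the gene of a cell cycle inhibitor, fell 1.72-fold (log2 difference -0.78, SE 0.13; adjusted p = 0.00214), and Fam124b fell 1.71-fold (adjusted p = 0.0132). The olfactory receptor gene Olfr1033 was 1.73-fold lower (adjusted p = 0.0227), but it has near-identical relatives, so which gene its probes read is uncertain. Its call was lost without WT ZT0 replicate 1, 5 or 6 or WT ZT12 replicate 1 or 3 (adjusted p 0.0501 to 0.0577). For each of these genes with the largest changes, clock genes included, all 7 ZT12 arrays lay on the called side of the ZT0 mean, and for all but Olfr1033 (3 of 7) they also lay beyond every ZT0 array.

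**Figure D1:**
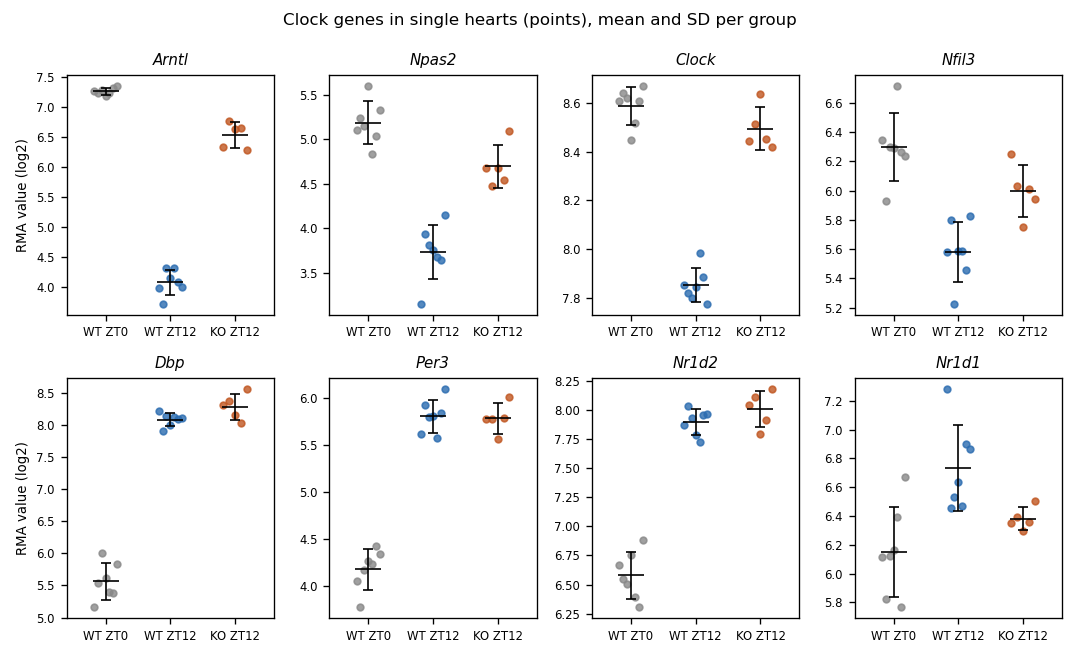
Log2 array intensity of 8 clock genes in each heart, by group (points, hearts; bars, group mean with SD; n = 7 for wild type at ZT0, 7 for wild type at ZT12 and 5 for knockout at ZT12). Arntl went from 7.27 at ZT0 to 4.08 at ZT12 in wild-type hearts and was at 6.54 in the knockout, while Dbp was at 5.56, 8.09 and 8.29.

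The clock genes moved as groups. Of 7 measured genes of the list repressed by REV-ERB proteins, 0 rose, 4 fell and 3 did not pass (0 higher and 4 lower adjusted over the list alone). Besides Arntl and Npas2, these were Clock (1.66-fold lower; adjusted p = 4.68e-08) and Nfil3 (1.64-fold lower; adjusted p = 0.000499). Log2 differences of -0.12 for Cry1, 0.26 for E2f8 and -0.38 for Pdk4 did not pass (adjusted p 0.391 to 0.732). Of 13 genes with E-box or D-box control, 12 rose, 0 fell and 1 did not pass (13 higher and 0 lower adjusted over the list alone). Per1 was 1.98-fold higher, Wee1 1.94-fold, Cry2 1.73-fold, Hlf 1.70-fold, Usp2 1.67-fold, Tef 1.65-fold and Bhlhe41 1.47-fold (adjusted p 7.02e-07 to 0.000293). Another, dim probe set of Tef was at a log2 difference of -0.18, and the call for Tef was lost when the probe sets of a gene were averaged (adjusted p = 0.0788). Bhlhe40, at 0.50, did not pass (adjusted p = 0.0536). Nr1d1, the gene of Rev-erb alpha, rose 1.501-fold (log2 difference 0.59, SE 0.13; adjusted p = 0.0289), a call lost without WT ZT0 replicate 1, 2, 3, 4 or 6 or WT ZT12 replicate 1, 6 or 7 (adjusted p 0.0521 to 0.0707). It was also lost with only the arrays compared (adjusted p = 0.0709) and without the 4 arrays low in atrial markers, which are described below (0.0512). Both clock lists shifted, the repressed list down (camera adjusted p = 2.47e-14, and adjusted p = 6.43e-06 with an estimated correlation) and the E-box list up (camera adjusted p = 1.22e-51, and adjusted p = 1.43e-06 with an estimated correlation). These calls held without any single array.

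Among stress and matrix genes, the unfolded protein response list shifted down at ZT12 (median log2 difference -0.18; camera adjusted p = 0.000125, but adjusted p = 0.445 with an estimated correlation). Of its 21 genes, 1 rose, 1 fell and 19 did not pass (1 higher and 11 lower adjusted over the list alone). The chaperone gene Hyou1 (log2 difference -0.44, adjusted p = 0.00160) fell and Herpud1 (log2 difference 0.31, adjusted p = 0.00766) rose. Extracellular matrix genes shifted down (median -0.12; camera adjusted p = 0.000860, but adjusted p = 0.769 with an estimated correlation), and of 23 genes 0 rose, 2 fell and 21 did not pass (0 higher and 4 lower adjusted over the list alone). The genes that fell were Col4a1 (log2 difference -0.47, adjusted p = 0.00686) and Eln (log2 difference -0.66, adjusted p = 0.0481), the call for Eln being lost without any compared array other than WT ZT12 replicate 1 (adjusted p 0.0622 to 0.106) and with the atrial list mean (0.130) or Bmp10 (0.180) as a covariate. Centring the arrays ended it as well (0.0533). The glucocorticoid-responsive list shifted up (median 0.30; camera adjusted p = 2.57e-06, but adjusted p = 0.110 with an estimated correlation), and of 20 genes 7 rose, 2 fell and 11 did not pass (11 higher and 2 lower adjusted over the list alone). Zbtb16 and Per1 belonged to it, as did Klf9 (log2 difference 0.46, adjusted p = 0.000888). Fatty acid and cholesterol synthesis genes shifted down (median -0.15; camera adjusted p = 0.0329, but adjusted p = 0.769 with an estimated correlation), although of 20 genes 0 rose, 0 fell and 20 did not pass (0 higher and 0 lower adjusted over the list alone), with Srebf2 at -0.24 and Lpin1 at -0.23. That list call was lost without WT ZT0 replicate 1 or 2 or WT ZT12 replicate 3, 4, 5 or 6 (adjusted p 0.0520 to 0.121). Atrial muscle markers, read by the same arrays, had a median of -0.59 in this comparison. With their mean as a covariate, the matrix and lipid synthesis calls were lost (adjusted p = 0.220 and 0.667), as they were with Bmp10 as a covariate (0.165 and 0.688). Without the 4 arrays low in atrial markers the lipid synthesis call was lost (adjusted p = 0.0539).

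Other lists did not shift past the threshold between the times of day, though some of their genes were called. Of 30 immediate early genes, 1 rose, 0 fell and 29 did not pass (1 higher and 0 lower adjusted over the list alone); Ier3 rose 1.43-fold (adjusted p = 0.0224), a call lost without WT ZT0 replicate 2 or 4 or WT ZT12 replicate 2, 4 or 6 (adjusted p 0.0521 to 0.0564). Of 32 genes of fatty acid uptake and oxidation, 0 rose, 2 fell and 30 did not pass (0 higher and 2 lower adjusted over the list alone). Acads fell (log2 difference -0.28, adjusted p = 0.0454), a call lost without any compared array other than WT ZT0 replicate 4 (adjusted p 0.0544 to 0.105) and with the atrial list mean (0.131) or Bmp10 (0.161) as a covariate. The lipid droplet gene Plin5 also fell (log2 difference -0.43, adjusted p = 0.0481), a call lost without any compared array other than WT ZT0 replicate 6 and WT ZT12 replicates 1 and 5 (adjusted p 0.0580 to 0.111) and with Bmp10 as a covariate (0.0994). Of 26 glycolysis genes, 1 rose, 0 fell and 25 did not pass (1 higher and 0 lower adjusted over the list alone). Pfkfb3 rose (log2 difference 0.56, adjusted p = 0.0398), a call lost without any compared array other than WT ZT0 replicates 3 and 7 and WT ZT12 replicates 3, 5 and 6 (adjusted p 0.0542 to 0.0932). Among 24 targets of hypoxia-inducible factors, which include Pfkfb3, 1 rose, 2 fell and 21 did not pass (3 higher and 4 lower adjusted over the list alone). Ddit4, which encodes an inhibitor of growth signalling, fell (log2 difference -0.68, adjusted p = 0.00661). Vegfa fell as well (log2 difference -0.36, adjusted p = 0.0289), a call lost without WT ZT0 replicate 1, 2, 5 or 6 or WT ZT12 replicate 1, 3, 5 or 7 (adjusted p 0.0503 to 0.0727). With only the arrays compared the calls for Acads, Plin5, Pfkfb3 and Vegfa were lost (adjusted p 0.0590 to 0.0713), as they were without the 4 arrays low in atrial markers (0.0552 to 0.0858). The replicate block ended those for Ier3, Acads, Plin5 and Vegfa (0.0627 to 0.0880), and centring those for Acads and Plin5 (0.0634 to 0.0842).

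Of 24 antioxidant genes, 2 rose, 0 fell and 22 did not pass (4 higher and 0 lower adjusted over the list alone). The metallothionein gene Mt2 rose (log2 difference 0.85, adjusted p = 0.0208), a call lost without WT ZT0 replicate 1 or WT ZT12 replicate 6 (adjusted p 0.0517 to 0.0533). Nqo1 rose (log2 difference 0.41, adjusted p = 0.0358), a call lost without any compared array other than WT ZT12 replicates 2, 5 and 7 (adjusted p 0.0513 to 0.0849) and with the atrial list mean (0.104) or Bmp10 (0.148) as a covariate. The replicate block ended both calls (0.0642 to 0.0805). Of 22 p53 targets, 0 rose, 1 fell and 21 did not pass (1 higher and 1 lower adjusted over the list alone), Cdkn1a being the gene that fell. Of 26 cardiac ion channel and calcium genes, 1 rose, 1 fell and 24 did not pass (1 higher and 1 lower adjusted over the list alone): Klf15 (log2 difference 0.46, adjusted p = 0.0185) rose and the gap junction gene Gja1 (log2 difference -0.33, adjusted p = 0.0122) fell. With Bmp10 as a covariate both calls were lost (adjusted p = 0.0770 and 0.0527), that for Klf15 also with the replicate block (0.0880). Among 14 fetal and stress genes, 0 rose, 1 fell and 13 did not pass (2 higher and 3 lower adjusted over the list alone), with a fall for Rcan1 (log2 difference -0.73, adjusted p = 0.00321). No member passed in the lists of heat shock (Chordc1 at -0.28, Hspb7 at 0.23), oxidative phosphorylation (Uqcrc1 at -0.16, Cox8b at -0.23), cytokines (Tnfaip3 at -0.55, Nlrp3 at -0.48), autophagy (Ctsd at -0.17, Lamp2 at 0.14) or cell division (Plk1 at -0.29, Mcm5 at 0.17), given as log2 differences. Adjusted over the list alone, these 5 lists had 0 genes passing. Median log2 differences were 0.11 for immediate early, -0.071 for heat shock, -0.032 for fatty acid oxidation, 0.020 for glycolysis and -0.011 for oxidative phosphorylation genes. They were 0.093 for p53, -0.026 for hypoxia, 0.015 for cytokine, 0.025 for antioxidant, 0.034 for autophagy, -0.025 for ion channel, -0.056 for fetal and 0.064 for cell division genes. Camera gave adjusted p between 0.0563 and 0.932 for these 13 lists. In the cytokine list the median and the mean (-0.030) differed in sign, the test pointing the way of the mean, and in the autophagy list the mean was -0.00064. In other settings some of these lists passed. Of 11 settings, upward shifts passed for p53 targets in 9 (adjusted p 0.0237 to 0.0488, dim probe sets left out and the replicate block excepted) and for immediate early genes in 8 (4.04e-06 to 0.0469, with centring as a further exception). They passed for antioxidant genes in 7 (0.0133 to 0.0488), both covariates among them. Downward shifts passed for oxidative phosphorylation in 3 (0.0283 to 0.0454) and, with the atrial list mean as a covariate, for heat shock (0.0167) and fatty acid oxidation (0.0308). All these passes used the preset correlation. With an estimated correlation over all arrays, adjusted p was 0.405 to 0.786 for the same lists. Immediate early genes vary together (estimated correlation 0.62). The autophagy test pointed up when the arrays were quantile normalized again or centred on their medians.

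Cell type markers described how alike the tissue samples were. Cardiomyocyte markers had a median log2 difference of 0.013, with Myl2 at -0.077 and Myl3 at -0.074. Of 12 endothelial markers, 0 rose, 1 fell and 11 did not pass (2 higher and 3 lower adjusted over the list alone), Kdr falling 1.44-fold (adjusted p = 0.00160). Atrial markers had a median of -0.59 and none passed, the nearest being Gpr22 at 0.38 and Bmp10 at -2.79. Fibroblast markers had a median of -0.12 (Col1a1 at -0.32, Gsn at -0.19), smooth muscle -0.11 (Cnn1 at -0.76, Acta2 at -0.36), macrophage -0.068 (Adgre1 at -0.28, Cd163 at 0.22) and neutrophil -0.055 (Csf3r at -0.19, S100a8 at -0.26). Lymphocyte markers were at 0.017 (Cd79a at -0.17, Cd3g at 0.15), the 2 erythroid markers at 0.0052 (Epb42 at 0.077, Slc4a1 at -0.067), adipocyte at -0.016 (Plin4 at 0.13, Fabp4 at 0.13) and mesothelium at -0.064 (Krt19 at -0.18, Msln at -0.18). Skeletal muscle markers were at -0.041 (Myl1 at -0.28, Myh4 at 0.15), lung and thymus at 0.0046 (Ptcra at 0.15, Themis at 0.16) and Schwann cell and neuron at -0.050 (Mbp at -0.16, Sox10 at -0.14). Camera called none of the 14 marker lists over all arrays (adjusted p 0.0628 to 0.902). The adipocyte list passed upward with the atrial list mean (adjusted p = 0.00624) or Bmp10 (0.0245) as a covariate, at the preset correlation. Its genes vary together (estimated correlation 0.66), and over all arrays its camera adjusted p with that correlation was 0.938. The atrial list passed downward in 4 of the 11 settings, among them that without the 4 arrays low in atrial markers (0.00810 to 0.0488), and the fibroblast list downward in 2 (0.0234 to 0.0417). These passes too used the preset correlation. With an estimated one over all arrays, camera gave both lists an adjusted p of 0.786. Adjusted over the list alone, 1 atrial gene (Gpr22, higher) passed, 2 endothelial genes were higher and 3 lower, and the other 12 marker lists had 0. In the adipocyte list the test pointed up while the median and mean (-0.069) were below 0. The muscle, atrial, vascular, fibroblast and mesothelial lists hold transcripts of the heart itself, so they describe the make-up of the samples.

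In this comparison 250 of 22180 genes changed between the wild-type groups, 143 higher and 107 lower at ZT12, and 71 of them by at least 1.5-fold. Without adjustment, 2549 genes were under 0.05. The call count stayed between 185 and 251 without any single array.

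The knockout was compared with wild type at ZT12, the time at which both genotypes were sampled, to ask what loss of Rev-erb alpha changes in the reperfused heart. The labels give no strain for the knockout mice. A difference in genetic background between the groups therefore cannot be told apart from loss of the gene. The targeted gene itself, Nr1d1, had a level of 6.15 ± 0.31 in wild type at ZT0 (SD, n = 7), 6.74 ± 0.30 in wild type at ZT12 (SD, n = 7) and 6.38 ± 0.077 in the knockout (SD, n = 5). It was 1.28-fold lower in the knockout, which did not pass (log2 difference -0.35, SE 0.15; adjusted p = 0.374), and all 5 knockout arrays lay below the wild-type ZT12 mean, 4 of them below every wild-type ZT12 array. Which part of the gene the probes read, and whether the targeted allele keeps it, is not given in the sources used here. Arntl, a direct target of repression by Rev-erb alpha, rose 5.48-fold, from 4.08 ± 0.21 in wild type to 6.54 ± 0.22 in the knockout (SD, n = 7 and 5). Npas2 was 1.95-fold higher (log2 difference 0.96, SE 0.15; adjusted p = 0.00170).

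Kcne1, which encodes a subunit of a cardiac potassium channel, rose 3.80-fold in the knockout, from 4.52 ± 0.24 to 6.45 ± 0.24 (SD, n = 7 and 5). The magnesium transporter gene Slc41a3 rose 3.39-fold (log2 difference 1.76, SE 0.10; adjusted p = 9.55e-10), Ddit4 rose 2.598-fold (log2 difference 1.38, SE 0.14; adjusted p = 8.27e-06) and Cdkn1a rose 2.17-fold (log2 difference 1.12, SE 0.15; adjusted p = 0.000246). Pdk4, whose product limits glucose oxidation, was 2.0-fold higher (log2 difference 1.0, SE 0.21; adjusted p = 0.0223), a call lost without KO ZT12 replicate 4 or 5 (adjusted p 0.0544 to 0.0585). Olfr1034 rose 1.91-fold (adjusted p = 0.0311), again with near-identical relatives and a call lost without WT ZT12 replicate 2, 4 or 7 or KO ZT12 replicate 2, 3, 4 or 5 (adjusted p 0.0529 to 0.0900). All 5 knockout arrays lay on the called side of the wild-type mean for each of the 16 genes with the largest changes. They also lay beyond every wild-type ZT12 array except for 1 or 2 arrays in Pdk4 (3 of 5 beyond), Ch25h, Slamf7, Scn4b and Nr4a3 (4 of 5 each).

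Mylk4, which encodes a kinase of the myosin light chain kinase family, fell 2.13-fold, from 7.96 ± 0.13 to 6.87 ± 0.21 (SD, n = 7 and 5). Acta1, the gene of skeletal alpha actin, was 3.38-fold lower (log2 difference -1.76, SE 0.36; adjusted p = 0.0242), a call lost without KO ZT12 replicate 2 or 5 (adjusted p 0.0633 to 0.0757). The cytokine gene Il33 fell 1.87-fold (log2 difference -0.90, SE 0.16; adjusted p = 0.00788), and the immune receptor gene Slamf7 fell 1.89-fold (adjusted p = 0.0144), its call lost without KO ZT12 replicate 4 (adjusted p 0.0510). Scn4b, a sodium channel subunit gene, was 1.83-fold lower (adjusted p = 0.0247), a call lost without KO ZT12 replicate 1, 2, 3 or 5 (adjusted p 0.0531 to 0.0655). Lrat, which encodes an enzyme of retinol storage, fell 1.83-fold (adjusted p = 0.0361), a call lost without WT ZT12 replicate 2, 3, 5 or 7 or KO ZT12 replicate 2, 4 or 5 (adjusted p 0.0560 to 0.114). Ch25h, an oxysterol enzyme gene, was 2.14-fold lower (adjusted p = 0.0442), while another, dim probe set of it was at 0.21. Its call was lost without any compared array other than WT ZT12 replicates 3 and 5 and KO ZT12 replicate 1 (adjusted p 0.0586 to 0.131). The nuclear receptor gene Nr4a3 fell 1.82-fold (adjusted p = 0.0442), a call lost without any compared array other than WT ZT12 replicates 1 and 5 and KO ZT12 replicate 1 (adjusted p 0.0585 to 0.117). When the 4 arrays low in atrial markers were left out, among these 16 genes the calls for Pdk4, Npas2, Olfr1034, Acta1, Ch25h, Slamf7, Il33, Scn4b, Lrat and Nr4a3 were lost (adjusted p 0.105 to 0.680), which left 2 knockout arrays. The log2 difference then shrank for Acta1 (-0.89, SE 0.37), Lrat (-0.43, SE 0.24), Pdk4 (0.63, SE 0.23) and Il33 (-0.62, SE 0.17), and for the other 6 it was 0.843 to 1.23 of the reported one, with larger SEs. With the atrial list mean as a covariate the calls for Olfr1034, Ch25h, Lrat and Nr4a3 were lost (adjusted p 0.0911 to 0.120), and with Bmp10 those for Olfr1034, Lrat and Nr4a3 (0.0605 to 0.0864). With only the arrays compared those for Pdk4, Acta1, Ch25h, Slamf7, Il33, Scn4b, Lrat and Nr4a3 were lost (0.0583 to 0.146). The replicate block ended those for Pdk4, Olfr1034, Ch25h, Scn4b and Nr4a3 (0.0708 to 0.174). The calls for Ch25h and Nr4a3 were lost with trend and robust (0.0628 to 0.0657), that for Ch25h also with averaged probe sets (0.220) and array weights (0.0640), and that for Nr4a3 with centring (0.0512).

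**Figure D2:**
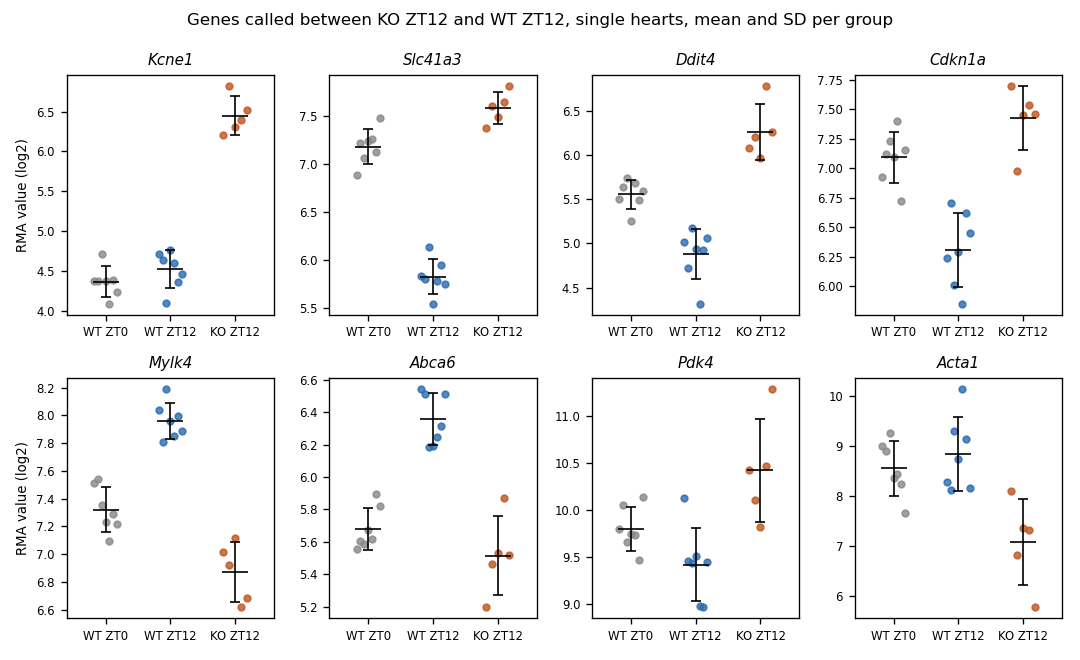
Log2 array intensity of 8 genes with large changes in the knockout in each heart, by group (points, hearts; bars, group mean with SD; n = 7, 7 and 5). Kcne1 averaged 4.52 in wild type and 6.45 in the knockout at ZT12, and Mylk4 7.96 and 6.87.

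Of 7 measured genes of the list repressed by REV-ERB proteins, 4 rose, 0 fell and 3 did not pass (6 higher and 1 lower adjusted over the list alone). This list also holds Pdk4 and E2f8, which are not core clock genes, and Pdk4 is in the fatty acid and glucocorticoid lists too. Clock rose 1.56-fold (adjusted p = 4.77e-06), beside Arntl, Npas2 and Pdk4, while Cry1 at 0.25, Nfil3 at 0.42 and E2f8 at -0.31 did not pass (log2 differences; adjusted p 0.119 to 0.442). The list shifted up (camera adjusted p = 2.25e-13), as it did with an estimated correlation (adjusted p = 1.76e-05) and without any single array. Of 13 E-box and D-box genes, 0 rose, 0 fell and 13 did not pass (0 higher and 0 lower adjusted over the list alone), and the list did not shift (camera adjusted p = 0.2005). Its log2 differences were 0.20 for Dbp, 0.12 for Per1, -0.025 for Per3, 0.20 for Cry2, 0.11 for Nr1d2, 0.25 for Ciart, -0.13 for Bhlhe40 and 0.23 for Bhlhe41. They were 0.21 for Tef, 0.18 for Hlf, -0.079 for Usp2 and -0.13 for Wee1. The plot of clock genes shows the 5 knockout hearts near the wild-type ZT12 hearts for Dbp and Per3 and above them for Arntl and Npas2.

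The list of fatty acid uptake and oxidation shifted up in the knockout (median log2 difference 0.10; camera adjusted p = 3.57e-07, but adjusted p = 0.371 with an estimated correlation) and of 32 genes 2 rose, 0 fell and 30 did not pass (6 higher and 0 lower adjusted over the list alone). Plin5, of the lipid droplet, rose 1.55-fold (adjusted p = 0.00808), beside Pdk4. This list call was lost without the 4 arrays low in atrial markers (adjusted p = 0.0887), and so was that for Plin5 (adjusted p = 0.341). The glucocorticoid-responsive list shifted up (median 0.23; camera adjusted p = 5.11e-11) and held with an estimated correlation (adjusted p = 0.0194). Of its 20 genes 6 rose, 0 fell and 14 did not pass (9 higher and 0 lower adjusted over the list alone), among them Ddit4, Cdkn1a and Pik3r1 (log2 difference 0.41, adjusted p = 0.00610), which lost its call without the 4 arrays low in atrial markers (adjusted p = 0.0837). Of 43 oxidative phosphorylation genes, 0 rose, 0 fell and 43 did not pass (0 higher and 0 lower adjusted over the list alone), with Ndufa1 at 0.22 and Cox6a2 at 0.41, and the list shifted up by a median of 0.023 (camera adjusted p = 0.0281, but adjusted p = 0.571 with an estimated correlation). That call was lost without WT ZT12 replicate 2 or KO ZT12 replicate 2 or 3 (adjusted p 0.0892 to 0.163), and without the 4 arrays low in atrial markers (0.0524). Of 22 autophagy and lysosome genes, 0 rose, 0 fell and 22 did not pass (1 higher and 0 lower adjusted over the list alone), with Lamp1 at 0.25 and Pink1 at 0.18, and the list shifted up by a median of 0.096 (camera adjusted p = 0.0287, but adjusted p = 0.220 with an estimated correlation). The autophagy call was lost without WT ZT12 replicate 1 or 4 or KO ZT12 replicate 1 (adjusted p 0.0643 to 0.0786), and without the 4 arrays low in atrial markers (0.0866). Quantile normalization repeated on the deposited values also ended the calls for oxidative phosphorylation (adjusted p = 0.254) and autophagy (adjusted p = 0.198).

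Few genes were called in the lists of stress and inflammation. Immediate early genes shifted down in the knockout (median -0.13; camera adjusted p = 0.00236, but adjusted p = 0.645 with an estimated correlation), and of 30 genes 0 rose, 1 fell and 29 did not pass (0 higher and 1 lower adjusted over the list alone), Nr4a3 being the gene that fell. The call was lost without WT ZT12 replicate 2 or KO ZT12 replicate 3 (adjusted p 0.0709 to 0.486). Cytokine genes shifted down (median -0.20; camera adjusted p = 0.00236, but adjusted p = 0.571 with an estimated correlation), and of 28 genes 0 rose, 0 fell and 28 did not pass (0 higher and 0 lower adjusted over the list alone), with Ccl2 at -0.79 and Il6 at -1.18. That call was lost without WT ZT12 replicate 2 or KO ZT12 replicate 3 (adjusted p 0.0512 to 0.0789). Heat shock genes shifted down (median -0.096; camera adjusted p = 0.0198, but adjusted p = 0.571 with an estimated correlation), and of 23 genes 0 rose, 0 fell and 23 did not pass (0 higher and 0 lower adjusted over the list alone), with Bag3 at 0.25 and Hspa1b at -0.57. The heat shock call was lost without WT ZT12 replicate 6 or KO ZT12 replicate 3 (adjusted p 0.0577 to 0.412). The unfolded protein response shifted down (median -0.078; camera adjusted p = 0.0281, but adjusted p = 0.571 with an estimated correlation), and of 21 genes 0 rose, 0 fell and 21 did not pass (1 higher and 2 lower adjusted over the list alone), with Atf4 at -0.42 and Asns at -0.29. Its call was lost without WT ZT12 replicate 2 or 7 or KO ZT12 replicate 2 or 5 (adjusted p 0.0634 to 0.102), and without the 4 arrays low in atrial markers (0.158). Cell division genes shifted down (median -0.11; camera adjusted p = 0.00236, but adjusted p = 0.220 with an estimated correlation), and of 19 genes 0 rose, 0 fell and 19 did not pass (0 higher and 1 lower adjusted over the list alone), with Kif11 at -0.37 and Ccnb2 at -0.27, a call that held without any single array but not without the 4 arrays low in atrial markers (adjusted p = 0.197). With the mean of the atrial markers as a covariate the calls for immediate early (adjusted p = 0.123), cytokine (0.242), unfolded protein response (0.182) and oxidative phosphorylation genes (0.0911) were lost. With Bmp10 as a covariate the same 4 were lost (adjusted p 0.0830 to 0.0917).

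The fetal and stress gene list did not shift past the threshold (median -0.042; camera adjusted p = 0.0534), and of its 14 genes 1 rose, 3 fell and 10 did not pass (1 higher and 3 lower adjusted over the list alone). Ankrd1 fell 1.36-fold (adjusted p = 0.0302) beside Acta1 and Il33, a call lost without WT ZT12 replicate 3, 4, 5 or 6 or KO ZT12 replicate 3, 4 or 5 (adjusted p 0.0512 to 0.104) and without the 4 arrays low in atrial markers (0.492). It was also lost with only the arrays compared (0.0914) and with the replicate block (0.0719). Of 26 ion channel and calcium genes, 0 rose, 1 fell and 25 did not pass (2 higher and 2 lower adjusted over the list alone), Scn4b being the gene that fell. Kcne1 is not in this list. The list median was 0.0093 with a mean of -0.083 (camera adjusted p = 0.530). Among 22 p53 targets, 1 rose, 0 fell and 21 did not pass (2 higher and 0 lower adjusted over the list alone), with a list median of -0.066 and Cdkn1a the gene that rose. Among 24 hypoxia targets, 1 rose, 0 fell and 23 did not pass (1 higher and 0 lower adjusted over the list alone), with a list median of 0.018 and Ddit4 the gene that rose. No gene passed for glycolysis (median -0.019; Pfkl at 0.34, Slc2a1 at -0.26), where 1 gene was higher adjusted over the list alone. None passed for antioxidant genes (median 0.053; Txnrd1 at -0.21, Gstp1 at 0.30), with 0 over the list alone. Matrix genes had a median of -0.040 and a mean of 0.0089 (Eln at 0.69, Lox at 0.49), with 2 higher and 1 lower adjusted over the list alone. Lipid synthesis genes had a median of -0.0041 and a mean of 0.075 (Srebf2 at -0.17, Insig1 at -0.23), with 0 over the list alone. In the ion channel, matrix and lipid synthesis lists the median and mean differed in sign. The test, which uses neither, pointed the way of the median for ion channel and lipid synthesis genes and of the mean for matrix genes. Camera gave adjusted p between 0.319 and 0.979 for these last 7 lists, the ion channel list among them. The other probe set of Slc2a1, a dim one, was at -0.079. Without the 4 arrays low in atrial markers the matrix and lipid synthesis lists passed upward (adjusted p = 5.34e-06 and 0.0195). The fetal and stress list passed downward in 5 of 11 other settings at the preset correlation (adjusted p 0.0295 to 0.0460). Its adjusted p with an estimated correlation over all arrays was 0.571. When the arrays were quantile normalized again the tests of the matrix and endothelial lists pointed down instead of up.

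Of the 14 cell type lists, 3 were called between the genotypes by camera with its preset correlation. Atrial markers shifted down in the knockout (median log2 difference -0.56; camera adjusted p = 0.0198, but adjusted p = 0.571 with an estimated correlation), though of 10 genes 0 rose, 0 fell and 10 did not pass (0 higher and 0 lower adjusted over the list alone), with Myl1 at -0.55 and Nppa at -0.57. The call was lost without WT ZT12 replicate 2 or 7 or KO ZT12 replicate 2, 4 or 5 (adjusted p 0.0512 to 0.163). Without the 4 arrays low in these markers, the list instead passed upward (adjusted p = 0.00972). The arrays were picked by this same list and 3 of them are knockout arrays, so leaving them out raises the knockout mean by selection. With 2 knockout arrays left, the turn says nothing about the direction of the list. The mean of the atrial list lay between 5.89 and 6.26 on wild-type ZT12 replicate 5 and knockout replicates 2, 4 and 5, and between 7.19 and 8.86 on the other 15 arrays. On those 4 arrays Sln was lower by 5.11, Bmp10 by 4.62, Myl7 by 4.23 and Myl4 by 1.87 on the log2 scale than on the others, while the median cardiomyocyte marker differed by 0.042. Macrophage markers shifted down (median -0.21; camera adjusted p = 0.0198, but adjusted p = 0.571 with an estimated correlation), and of 13 genes 0 rose, 0 fell and 13 did not pass (0 higher and 1 lower adjusted over the list alone), with Cd14 at -0.41 and Ly6c2 at 0.35. The macrophage call was lost without WT ZT12 replicate 1 or KO ZT12 replicate 5 (adjusted p 0.0695 to 0.449), and without the 4 arrays together (0.749). Neutrophil markers shifted up (median 0.075; camera adjusted p = 0.0296, but adjusted p = 0.220 with an estimated correlation), and of 10 genes 1 rose, 0 fell and 9 did not pass (1 higher and 0 lower adjusted over the list alone). Lcn2 rose 1.85-fold (adjusted p = 0.0179), a call lost without KO ZT12 replicate 2 or 3 (adjusted p 0.0506 to 0.0526), with only the arrays compared (0.0807) and with the replicate block (0.0937). The list call was lost without WT ZT12 replicate 3 or 4 or KO ZT12 replicate 1, 2 or 3 (adjusted p 0.0513 to 0.130). With the mean of the atrial markers as a covariate the calls for macrophage (adjusted p = 0.186) and neutrophil markers (adjusted p = 0.0777) were lost, and with Bmp10 those for macrophage (0.0830) and atrial markers (0.210).

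**Figure D3:**
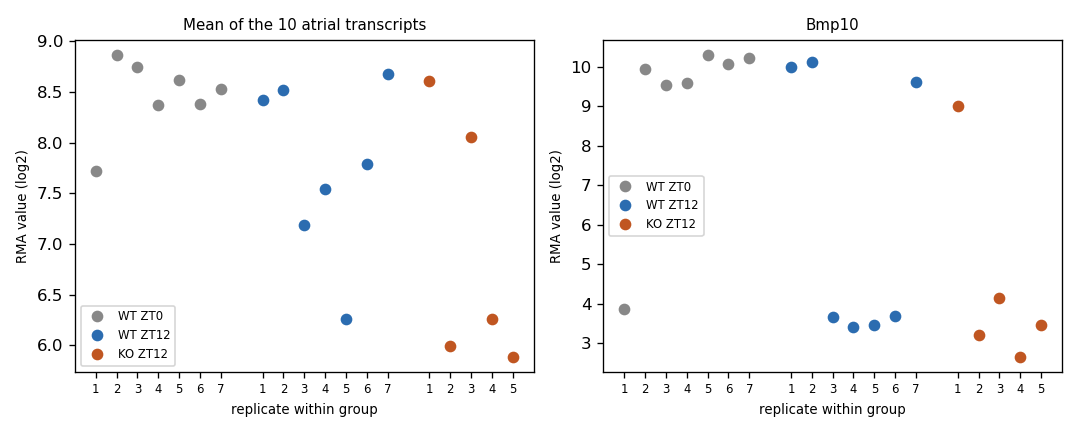
Mean log2 intensity of the 10 atrial marker genes and log2 intensity of Bmp10 in each heart, by group (points, hearts; n = 7, 7 and 5). The list mean was 5.89 to 6.26 on 4 arrays, 1 wild-type and 3 knockout, and Bmp10 was 2.66 to 4.15 on 9 arrays and 9.01 to 10.30 on the other 10.

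Adipocyte markers had a median of 0.21 and of 10 genes 1 rose, 0 fell and 9 did not pass (1 higher and 0 lower adjusted over the list alone), Plin4 rising 1.37-fold (adjusted p = 0.0223), a call lost without KO ZT12 replicate 2, 4 or 5 (adjusted p 0.0541 to 0.0626) and without the 4 arrays low in atrial markers (0.475). Mesothelial markers had a median of -0.16 and of 9 genes 0 rose, 1 fell and 8 did not pass (0 higher and 1 lower adjusted over the list alone), Lrrn4 falling 1.44-fold (adjusted p = 0.0359), a call lost without any compared array other than WT ZT12 replicates 3 and 5 and KO ZT12 replicates 1 and 3 (adjusted p 0.0653 to 0.110) and without the 4 arrays low in atrial markers (0.475). The atrial list mean (0.0989) or Bmp10 (0.0501) as a covariate and the replicate block (0.173) ended it too. Cardiomyocyte markers were at a median of 0.028 (Ryr2 at 0.21, Myl2 at 0.18), endothelial at 0.0095 (Kdr at 0.27, Cdh5 at -0.14), fibroblast at -0.0039 (Pi16 at -0.38, Col1a1 at 0.27) and smooth muscle at 0.0019 (Myh11 at 0.26, Cnn1 at 0.54). Lymphocyte markers were at -0.074 (Cd3g at -0.30, Nkg7 at -0.24), erythroid at -0.027 (Epb42 at -0.056, Slc4a1 at 0.0016), skeletal muscle at -0.10 (Myl1 at -0.55, Tnnc2 at -0.27), lung and thymus at -0.0039 with a mean of 0.017 (Sftpb at 0.25, Themis at -0.093) and Schwann cell and neuron at -0.049 (Chga at -0.15, Mbp at 0.11). The lung and thymus test pointed the way of the mean. Over all arrays camera called none of these 11 lists (adjusted p 0.0725 to 0.943). The adipocyte list passed upward with the atrial list mean (adjusted p = 2.65e-07) or Bmp10 (0.00109) as a covariate and without the 4 arrays low in atrial markers (1.66e-06), and the fibroblast list without those 4 arrays (0.00357). These tests used the preset correlation. Adipocyte genes vary together (estimated correlation 0.66), and over all arrays the list's camera adjusted p with that correlation was 0.645. The adipocyte mean was 6.80 on KO ZT12 replicate 1, 4.71 to 5.64 on the other knockout arrays and 4.66 to 6.47 on WT ZT12 arrays. Also at the preset correlation, adipocyte markers passed with the replicate block (0.0410), cardiomyocyte markers upward with trend and robust (0.0304) and skeletal muscle markers downward without dim probe sets (0.0462). Adjusted over the list alone 1 cardiomyocyte gene (Ryr2) was higher and the other 8 lists of the 9 without a called gene had 0.

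In the knockout 162 of 22180 genes changed against wild type at ZT12, 98 higher and 64 lower, 53 of them by at least 1.5-fold. Without adjustment, 2342 genes were under 0.05. The count fell to 105 without wild-type ZT12 replicate 2 or 4, and to 100, 107, 98 and 94 without knockout replicates 2, 3, 4 and 5. It was 19 when the 4 arrays low in atrial markers were left out together. All 162 genes then kept their sign, with a median ratio to the reported log2 difference of 0.970, and the median SE of the 148 lost calls went from 0.094 to 0.13. The 70 ways of leaving out 3 knockout arrays and 1 wild-type ZT12 array gave 16 to 137 (median 30).

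The knockout at ZT12 was also set against wild type at ZT0, where genotype and time of day differ together. Dbp was 6.61-fold higher in the knockout, at 8.29 ± 0.20 against 5.56 ± 0.29 (SD, n = 5 and 7). Kcne1 was 4.23-fold higher (log2 difference 2.08, SE 0.12; adjusted p = 7.37e-10), Zbtb16 3.82-fold (log2 difference 1.94, SE 0.10; adjusted p = 1.09e-10) and Ciart 3.29-fold (log2 difference 1.72, SE 0.17; adjusted p = 2.42e-06). The largest falls were those of Acta1 (2.77-fold; adjusted p = 0.0458), the G protein gene Gnao1 (1.97-fold; adjusted p = 0.0426), the ephrin receptor gene Epha4 (1.88-fold; adjusted p = 2.55e-05) and the myosin light chain gene Myl1, of the atrial and skeletal muscle lists (1.77-fold; adjusted p = 0.0394). The call for Acta1 was lost without any compared array other than WT ZT0 replicate 7 and KO ZT12 replicate 1 (adjusted p 0.0619 to 0.150), and that for Gnao1 without any compared array other than WT ZT0 replicate 7 and KO ZT12 replicates 1 and 3 (adjusted p 0.0553 to 0.130). For Myl1 it was lost without WT ZT0 replicate 1, 2, 3 or 5 or KO ZT12 replicate 2, 4 or 5 (adjusted p 0.0598 to 0.130). All 3 were also lost without the 4 arrays low in atrial markers (adjusted p 0.512 to 0.890) and with the atrial list mean (0.177 to 0.537) or Bmp10 (0.0612 to 0.394) as a covariate. They were lost with only the arrays compared (0.0543 to 0.117) and the replicate block (0.0572 to 0.108) too, those for Acta1 and Gnao1 with trend and robust (0.0689 to 0.0831) and that for Gnao1 with array weights (0.0504). In all 5 knockout arrays each of these 8 genes lay on the called side of the ZT0 mean, except Gnao1 (4 of 5).

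Of 13 E-box and D-box clock genes, 11 rose, 0 fell and 2 did not pass (12 higher and 0 lower adjusted over the list alone). The list shifted up (camera adjusted p = 1.17e-46, and adjusted p = 2.89e-06 with an estimated correlation). In the list repressed by REV-ERB proteins 0 rose, 1 fell and 6 did not pass (1 higher and 3 lower adjusted over the list alone), Arntl lying 1.66-fold below its ZT0 level (camera adjusted p = 0.0425, and adjusted p = 0.245 with an estimated correlation). The glucocorticoid-responsive list was higher (median log2 difference 0.62; camera adjusted p = 1.80e-24, and adjusted p = 0.000356 with an estimated correlation), and of 20 genes 10 rose, 0 fell and 10 did not pass (16 higher and 1 lower adjusted over the list alone). The unfolded protein response was lower (median -0.26; camera adjusted p = 4.41e-09, and adjusted p = 0.131 with an estimated correlation), and of 21 genes 1 rose, 7 fell and 13 did not pass (1 higher and 14 lower adjusted over the list alone). Atrial markers were lower too (median -1.02; camera adjusted p = 6.70e-05, and adjusted p = 0.303 with an estimated correlation), and of 10 genes 1 rose, 1 fell and 8 did not pass (1 higher and 8 lower adjusted over the list alone).

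Camera called 17 of the 33 lists in this comparison, the 5 above and 12 others. These 12 are given with the median log2 difference, the camera adjusted p and the adjusted p with an estimated correlation. Lower in the knockout were heat shock (-0.16; 0.000241, 0.303), cytokine (-0.22; 0.000851, 0.448), fetal and stress (-0.18; 0.00334, 0.270), matrix (-0.17; 0.00229, 0.448), lipid synthesis (-0.094; 0.0374, 0.452) and cell division (-0.11; 0.0252, 0.303) genes. Markers were lower for fibroblast (-0.12; 0.0466, 0.556), macrophage (-0.34; 0.00412, 0.362) and mesothelial (-0.23; 0.0172, 0.362) cells. Higher were fatty acid oxidation (0.093; 0.00160, 0.448), antioxidant (0.074; 0.00429, 0.270) and autophagy (0.057; 0.0425, 0.270) genes. Of the 17 lists, those of E-box genes and glucocorticoid response also passed with an estimated correlation. Of these calls, 8 depended on single arrays. That of the list repressed by REV-ERB proteins was lost without WT ZT0 replicate 1, 3, 6 or 7 or KO ZT12 replicate 2, 3 or 4 (adjusted p 0.0558 to 0.111). The autophagy call was lost without WT ZT0 replicate 1, 4 or 6 or KO ZT12 replicate 1, 4 or 5 (adjusted p 0.0524 to 0.0979), and that for lipid synthesis without WT ZT0 replicate 1 or 2 or KO ZT12 replicate 2, 3, 4 or 5 (adjusted p 0.0554 to 0.199). For cell division it was lost without WT ZT0 replicate 5 or 6 or KO ZT12 replicate 2 or 5 (adjusted p 0.0557 to 0.111). For fibroblast markers it was lost without WT ZT0 replicate 2, 3 or 6 or KO ZT12 replicate 4 or 5 (adjusted p 0.0812 to 0.802), and for mesothelium without WT ZT0 replicate 3 or KO ZT12 replicate 2, 4 or 5 (adjusted p 0.0673 to 0.140). The matrix and macrophage calls were lost without KO ZT12 replicate 5 (adjusted p = 0.282 and 0.117). Without the 4 arrays low in atrial markers 5 of the 17 calls were kept (E-box, heat shock, antioxidant, unfolded protein response and glucocorticoid response). For the other 12, atrial markers included, adjusted p was 0.107 to 0.913. For the atrial list itself this follows from how the arrays were picked. The same 5 were kept with the atrial list mean as a covariate (0.101 to 0.825 for the others). With Bmp10 fatty acid oxidation, fetal and cell division genes were kept as well (0.0766 to 0.951 for the other 9). Adipocyte markers, not called over all arrays (camera adjusted p = 0.0670, and 0.584 with their estimated correlation of 0.66), passed upward in these 3 settings at the preset correlation (2.71e-11 to 7.38e-07). Immediate early genes passed with Bmp10 (0.0387) and without the 4 arrays (0.00552), also at the preset correlation. Over all arrays their adjusted p with an estimated correlation was 0.884.

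Between these groups 298 of 22180 genes differed, 214 higher and 84 lower in the knockout, 90 of them by at least 1.5-fold, and 2793 were under 0.05 without adjustment. The count was 195 without wild-type ZT0 replicate 5, and 171 and 192 without knockout replicates 4 and 5. Without the 4 arrays low in atrial markers it was 84, with Bmp10 as a covariate 134 and with the atrial list mean as a covariate 162.

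The last comparison asked which genes differed from wild type at ZT12 in the same direction in the knockout and in wild type at ZT0. Arntl was higher in both, by 3.18 at ZT0 and 2.45 in the knockout (log2 differences from wild type at ZT12). So were Slc41a3 (1.36 and 1.76), Npas2 (1.45 and 0.96), Cdkn1a (0.78 and 1.12) and Fabp7, a brain-type fatty acid binding protein gene (0.74 and 0.88). Lower in both were Mylk4 (-0.64 and -1.09), the lipid transporter gene Abca6 (-0.68 and -0.84), the phosphodiesterase gene Gpcpd1 (-0.70 and -0.57), the drug transporter gene Abcb1a (-0.51 and -0.55) and the chemokine receptor gene Ackr4 (-0.47 and -0.53). In the comparison of genotypes the calls for Gpcpd1, Abcb1a and Ackr4 were lost without the 4 arrays low in atrial markers (adjusted p 0.100 to 0.214). With only the arrays compared those for Abcb1a and Ackr4 were lost (0.0544 to 0.0622), and that for Ackr4 with the replicate block (0.0762).

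Of 43 genes called in both comparisons, 39 went the same way, 29 higher and 10 lower than in wild type at ZT12, and 4 (Bmp4, Pik3r1, Thra and Zbtb16) went opposite ways. Between the genotypes the calls for all 4 were lost without the 4 arrays low in atrial markers (adjusted p 0.0837 to 0.339). Those other than Pik3r1 were also lost with the atrial list mean (0.0547 to 0.110) or Bmp10 (0.0698 to 0.0758) as a covariate. The same calls were lost with only the arrays compared, with array weights and with the replicate block. Quantile normalization again ended that for Bmp4, and centring that for Thra. The call for Bmp4 was lost without any compared array other than WT ZT12 replicates 2 and 6 and KO ZT12 replicate 2 (adjusted p 0.0653 to 0.133), and that for Thra without any compared array other than WT ZT12 replicate 5 and KO ZT12 replicate 2 (adjusted p 0.0506 to 0.120). For Zbtb16 it was lost without any compared array other than WT ZT12 replicates 3 and 7 and KO ZT12 replicate 2 (adjusted p 0.0661 to 0.115). Between the times of day that for Thra was lost without WT ZT0 replicate 2 or 4 or WT ZT12 replicate 3 (adjusted p 0.0502 to 0.0543) and with the atrial list mean (0.0701) or Bmp10 (0.0786). Both comparisons used the same 7 wild-type ZT12 arrays, which links them. Independent calls would give 0.473 genes higher and 0.413 lower in both, and simulated groups without differences that shared controls gave at most 1. Hardly any gene was called in those simulated groups, so they could not show how many real calls the shared arrays bring together. Across genes the log2 differences had a Pearson correlation of 0.371, against a median of 0.460 in the simulated groups, so the shared arrays alone gave such a value, and genes are not independent replicates. With the wild-type ZT12 arrays divided between the comparisons, in all 70 ways, 8 to 17 genes were shared (median 12), where independent calls would give at most 0.2498. The correlation across genes was then -0.058 to 0.134. Each comparison had 3 or 4 wild-type ZT12 arrays in these fits, and fewer genes were called, 73 to 191 between times of day and 31 to 111 between genotypes. How much of the lower shared count came from the smaller groups was not tested. The count of 39 was 25 without wild-type ZT12 replicate 3 and 11 without the 4 arrays low in atrial markers.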

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

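Tests on the number of gene lists called, on the atrial markers in all knockout hearts, and on the atrial list mean as a covariate were chosen only after the result was seen. In 38 of 519 values tested, 1 array lay apart from the rest of its group, where chance flags about 1 in 20 groups, which is 25.95. The value given is the gap to the nearest array divided by the range of the group. Among WT ZT0 arrays, replicate 1 was low for Bmp10 (0.882) and Lrrn4 (0.605), and replicate 3 was low for Abcb1a (0.614) and high for Myh11 (0.672), Uqcrc1 (0.654) and the mean of the list mesothelium (0.595). In the same group, replicate 5 was low for Fabp7 (0.589) and high for Herpud1 (0.767) and Ly6c2 (0.629), and replicate 6 was high for Gja1 (0.582) and low for Hspb7 (0.570). Among WT ZT12 arrays, replicate 1 was high for Col1a1 (0.636), replicate 2 was high for Bhlhe40 (0.637) and Txnrd1 (0.668) and low for Ciart (0.619) and the mean of the list oxidative phosphorylation (0.662), replicate 3 was low for Lox (0.626), and replicate 4 was high for Bhlhe41 (0.659) and Epb42 (0.588). In the same group, replicate 5 was low for Cry2 (0.579), Nppa (0.666), Pink1 (0.634), Tnfaip3 (0.669) and Uty (0.662), replicate 6 was high for E2f8 (0.575), and replicate 7 was high for Asns (0.585), Insig1 (0.708) and Mcm5 (0.765). Among KO ZT12 arrays, replicate 1 was high for Bmp10 (0.765), Il6 (0.722) and Txnrd1 (0.734) and low for the mean of the list cardiomyocyte (0.742), and replicate 3 was low for Hspa1b (0.738) and Plin4 (0.737) and high for Olfr1033 (0.8291). In the same group, replicate 4 was high for Scn4b (0.819) and low for Sox10 (0.8001), and replicate 5 was high for Ndufa1 (0.774). Among 17824 probe sets outside the gene test, which list several genes or none, 2 were called between the times of day, 11 between knockout and wild type at ZT12, and 18 between knockout and wild type at ZT0. Further probe sets of tested genes were not counted here.

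The numbers of called genes were set against 100 splits of the same arrays. Between the times of day 1 of the 100 splits, the real one, gave as many as 250 genes, and the highest other gave 1. For knockout against wild type at ZT12 it was 1 of 100 (162 genes, highest other 54), and against wild type at ZT0 1 of 100 (298 genes, highest other 43). A share of 1 in 100 is the lowest that this number of splits can give. Mixed groups also keep the real differences within them, which widens their spread and lowers their counts. The counts of genes therefore speak against chance without excluding it. The number of gene lists called by camera was different: between the times of day 21 of 100 splits called as many as the real 6 (highest other 11), and between the genotypes 7 of 100 called as many as the real 13 (highest other 16). For the number of lists the splits therefore do not speak against chance.

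The atrial markers were low on 4 arrays, 1 wild-type and 3 knockout arrays at ZT12, with cardiomyocyte markers differing by a median of 0.042. Bmp10 was low on 9 arrays, 5 of which (WT ZT0 replicate 1, WT ZT12 replicates 3, 4 and 6, and KO ZT12 replicate 3) were outside those 4. Of these 5, WT ZT12 replicate 3 had Myl7 at 7.49, below the 8.31 to 9.70 of the 10 arrays high in Bmp10. Its atrial signal was thus low beyond Bmp10. The other 4 had Myl7 at 8.65 to 9.30. A loss of atrial transcripts in all knockout hearts was argued against, since 2 knockout arrays lay within the range of the 13 other wild-type arrays. Uneven atrial tissue as the whole cause of the called genes was argued against only weakly: the median ratio of adjusted to reported log2 differences was 0.987 between genotypes with the atrial list mean as a covariate, and with Bmp10 it was 0.994 between genotypes (109 of 162 calls kept) and 1.01 between times of day (179 of 250 kept). A gene that follows atrial content varies within the groups and is called less readily, which favours ratios near 1. Between genotypes 0 of 10 atrial markers were called. The ratios say nothing of genes that were not called. The atrial list mean still ended 65 of the 162 calls, whose median size went from 0.45 to 0.41 and median SE from 0.097 to 0.11, so that smaller sizes and larger SEs both entered the lost calls. Why both moved was not tested. Less atrial tissue in the 4 samples may explain their markers but stays open, since for 3 of 5 atrial transcripts outside the list (Kcnj3, Sbk2 and Pam) all 4 arrays were among the 5 lowest, a test that replaced an earlier one on genes of the list itself. A missing right atrium may explain the 5 arrays with low Bmp10, as Hamp, also a right-atrial transcript, was above the median of the 10 arrays high in Bmp10 (6.36) on 0 of them, but on WT ZT12 replicate 6 it was 5.55, near the lowest of those 10 (5.74) and apart from the other 4 (2.61 to 3.59), so for that array it stays open.

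DNA of another strain around the targeted Nr1d1 locus could change genes in the knockout without Rev-erb alpha. Of the 200 nearest tested genes on chromosome 11, 2 were called, Med1 (log2 difference 0.39, adjusted p = 0.0465) and Thra (log2 difference -0.37, adjusted p = 0.0401), which is 1% against 0.729% of the other genes (odds ratio 1.37, one-sided Fisher's exact p = 0.431). Both calls were lost without the 4 arrays low in atrial markers (adjusted p = 0.450 and 0.216), and with the atrial list mean (0.124 and 0.110) or Bmp10 (0.0887 and 0.0758) as a covariate. The call for Med1 was also lost without any compared array other than WT ZT12 replicate 3 and KO ZT12 replicate 1 (adjusted p 0.0683 to 0.132) and that for Thra without any compared array other than WT ZT12 replicate 5 and KO ZT12 replicate 2 (adjusted p 0.0506 to 0.120). Both were lost with centring, only the arrays compared, array weights and the replicate block, and that for Med1 with quantile normalization again. The calls are too few to decide the question. A difference in background over the whole genome would also raise calls among the other genes, so this test could not show it. Thra is the nearest tested neighbour of Nr1d1 on its side, and an effect of the targeted allele on it was not tested.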

How the results depend on the processing

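The atrial list mean or Bmp10 as a covariate and leaving out the 4 arrays with low atrial markers were chosen only after the result was seen. The other settings were fixed before the data were examined, and with 1 value per gene no called gene changed its sign in them. Of the settings added later, leaving out the 4 arrays turned the atrial list, lower in the knockout over all arrays (adjusted p = 0.0198), to higher (adjusted p = 0.00972). These arrays were picked by the mean of that list, so the turn follows from the selection.

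Between the times of day, 250 genes were called, and 383 without dim probe sets, 71 at 1.5-fold or more and 115 at an adjusted p under 0.01. Leaving out single arrays gave 185 to 251. Other settings gave 171 to 374.

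Between knockout and wild type at ZT12, 162 genes were called. It was 264 without dim probe sets (fewer genes tested), 72 with only the arrays compared, 270 with trend and robust, 53 at 1.5-fold or more, 50 at an adjusted p under 0.01 and 19 without the 4 arrays low in atrial markers, which leaves 2 knockout arrays. Leaving out single arrays gave 94 (KO ZT12 replicate 5) to 161, with 105 without WT ZT12 replicate 2 or 4 and 100, 107 and 98 without KO ZT12 replicates 2, 3 and 4. Of the 162 genes, 158 were kept with trend and robust, 70 with only the arrays compared and 14 without the 4 arrays, where all 162 kept their sign with a median ratio of 0.970 to the reported log2 difference. The 148 lost calls went from a median size of 0.47 to 0.46 and a median SE of 0.094 to 0.13. Of the 70 ways to leave out as many arrays, 11 gave as few as 19. The cause was not tested for the change with only the arrays compared.

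Between knockout at ZT12 and wild type at ZT0, 298 genes were called. The count was 456 without dim probe sets, 187 with only the arrays compared, 162 with the atrial list mean and 134 with Bmp10 as a covariate, 84 without the 4 arrays, 90 at 1.5-fold or more and 119 at an adjusted p under 0.01. Leaving out single arrays gave 171 (KO ZT12 replicate 4) to 311, with 195 without WT ZT0 replicate 5 and 192 without KO ZT12 replicate 5. The cause was not tested for the change with only the arrays compared or with the covariates.

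The 39 shared genes became 62 without dim probe sets, 24 with only the arrays compared, 60 with trend and robust, 11 without the 4 arrays and 12 (median) with the WT ZT12 arrays divided, which left 3 or 4 of them per comparison. Leaving out single arrays gave 25 (WT ZT12 replicate 3) to 40. Of 19 gene lists called between the times of day (6) and between the genotypes (13), 4 were called by camera with an estimated correlation and 6 by fry. Lists called between knockout at ZT12 and wild type at ZT0 are not in these counts. Without single arrays 16 to 23 were called. Other settings called 16 to 27 lists, with 17 for the atrial list mean and 18 for Bmp10 as a covariate. The log2 difference of Nr1d1 in the knockout was -0.26 to -0.45 over all settings and stayed outside the threshold (adjusted p 0.264 to 0.588). Leaving out single arrays gave -0.26 to -0.40.

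With a replicate block the counts were 171, 88, 182 and 22, in the order above, 16 lists were called, and Nr1d1 was at -0.31. Hearts that share a replicate number did not pair (correlations of their residuals -0.072 to 0.074), and the block takes up degrees of freedom without removing a shared effect. Of the 162 calls between genotypes, 81 were kept with it.

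With quantile normalization again, 180 values of named genes kept their call or lack of it and 1 gained it. With only the arrays compared 159 were kept, 2 gained and 20 lost a call. Without the 4 arrays, 152 were kept, 3 gained and 26 lost a call. Leaving out single arrays kept 2163, with 7 gained and 172 lost. Of 43 named calls between the times of day 33 held without any single array, as did 16 of 28 between genotypes and 5 of 8 between knockout and wild type at ZT0. The low signal of many probe sets, with array medians near 3.3, limits what dim genes can show.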

Other observations

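Tests on glucocorticoid-responsive genes were chosen only after the result was seen. Glucocorticoid-responsive genes were higher in knockout than in wild type at ZT12, and the list holds 2 genes of the clock lists and several with other inducers. Stronger glucocorticoid signalling in the knockout animals was put to 9 members that are typical of this hormone (Tsc22d3, Fkbp5, Sgk1, Klf9, Per1, Zbtb16, Errfi1, Map3k6 and Sult1a1). All 9 had higher means in the knockout, but they belong to the list in which the rise was seen, so they cannot support that explanation. Uneven atrial tissue was argued against, as the median of the list was 0.31 with the atrial list mean as a covariate and 0.23 without it. Stronger hormone signalling stays open, since hormone levels were not measured and no genes outside the list were tested, and so does a direct effect of Rev-erb alpha on these genes, which was not tested.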
